A study of Mus musculus with 93 samples.

How the data were processed

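Single cells of mouse olfactory epithelium were sequenced from amplified poly(A) RNA, 93 libraries of 85 cells in 5 stages. Per the submitters' processing notes, reads of the mm10 genome were handled with CASAVA 1.8.2, Trim Galore, cutadapt 1.2.1, TopHat2 2.0.14 and Cufflinks 2.2.1; their settings and any scaling between libraries are not given in the sources used here. The authors' gene table holds FPKM for 32975 entries in 93 libraries, and all its columns were used. The authors also deposited a shorter table of 134 receptor and cell pairs (64 cells, 128 receptors), whose FPKM are those of the gene table and whose Pseudotime is a score without unit. How the pairs were chosen is not given, their FPKM served as an alternative, and the score was not analysed here. The deposited annotation gives genomic positions on mm10 (other values) for a basic GENCODE gene set, control sequences and assembled Olfr transcripts.

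Genes with more than 1 entry were taken once per symbol, which left 31528 genes. Olfr genes were those whose symbol starts with Olfr, pseudogenes included: 1175 entries for 1112 symbols, of which 186 entries were assembled transcripts. For the 55 symbols with more than 1 entry the highest FPKM was used. In all, 200 symbols reached an FPKM of 1 in a cell. The tables hold no counts, so the depth of a library was recovered from the step between low FPKM values of 2167 single exon genes of 800 to 4000 bp, which are multiples of 1 fragment (tolerance 5%, at least 5 genes). PCR copies are not independent molecules, so intervals cover counting error only.

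The first library of each cell was used. A gene was detected at an FPKM of at least 1. For each of 5 pairs of stages, the difference of mean log2(FPKM + 1) over cells, second stage minus first, was taken for genes detected in at least 50% of the cells of either stage. Shares of cells have exact Clopper-Pearson 95% intervals. No test between stages, standard error or p-value was computed, because a stage counts as 1 sample. Single cells far from the rest of a group of 4 to 10 values were picked out by the gap to the next value over the range, against Dixon's 95% critical values. Olfr genes per cell, their summed FPKM, the share of the top receptor and its ratio to the second are given per stage. For co-location, pairs of Olfr genes of a cell on the same chromosome or within 1 Mb were compared with 10000 draws of as many Olfr genes from those seen in any cell, with cells weighted equally. These draws treat cells as independent. Where the text gives a percentage against such draws, it is a description and not a test.

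Before the data were examined, the stages, the design, 20 gene lists and the rule for named genes were fixed. The lists were progenitor, precursor, immature neuron, mature neuron and odorant transduction, cell cycle, receptor choice and expression regulators, unfolded protein response, chromatin regulators, cilia, axon guidance, synapse, sustentacular cells, horizontal basal cells, glands and microvillous cells, glia and ensheathing cells, blood and immune cells, stromal and endothelial cells, dissociation stress, other chemosensory receptors and housekeeping. Each list was summarised by its median difference, the number of members higher and lower, and 10000 random lists of the same size matched on mean expression in 20 bins. A list with fewer than 3 measured members has no median: horizontal basal and glia lists had at most 1 measured member in any pair, and the stromal list 0. Named genes were, per pair, the 8 highest and the 8 lowest differences among annotated genes (no Olfr, Gm, Rik, ribosomal protein or mitochondrial gene), up to 4 members of each list with the largest differences, and 16 genes followed over all stages. A few other genes that met these rules are not reported here. Named receptors were the top receptor of the 3 cells with most Olfr genes per stage, those leading more than 1 cell, and those leading a cell with a repeat. Second receptors of a cell, receptors of D411 and D424, top receptors at an FPKM under 100, and Olfr genes beside the top receptor were named after their values were seen.

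The procedure was tested on simulated data for the same cells and genes. For gene differences, values were normal, with the mean and SD of each gene, and drawn independently for each gene. Lists whose members vary together over cells were thus not tested. Genes moved by 1 log2 unit were recovered with a mean of 0.94 for Progenitor to Precursor (right sign for 86%) and 1.02 for Precursor to Early Immature Neuron (90%). The means were 0.95 for Early to Late Immature Neuron (90%), 1.01 for Late Immature Neuron to Mature Neuron (87%) and 1.02 for Progenitor to Mature Neuron (86%). Genes moved by 3 units were recovered at 3.00, 2.92, 2.87, 2.97 and 2.93. A list of 20 genes moved by 1 unit lay at percentile 100, 99.99, 99.87, 100 and 99.9 of random lists, and a list of unmoved genes at 43.5, 68.8, 62.0, 53.7 and 9.66. Random receptor sets lay at percentile 37.4 for co-location and sets of neighbours at 100, and simulated depths were recovered at a ratio of 1. The receptor sets were drawn for each cell on its own, so receptors shared between cells were not simulated.

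Alternatives fixed beforehand were other FPKM thresholds, the mean of both libraries or the repeat in place of the first, rescaling each library to the same FPKM sum, leaving out Olfr pseudogenes, the authors' receptor table, leaving out cells of few genes and leaving out each cell in turn. For gene differences and co-location they were pseudocounts of 0.1 and 10, medians over cells, no detection filter, a window of 100 kb, pairs within 50 kb left out and draws from all annotated Olfr genes. Chosen after seeing the data were shuffling receptor positions once for all cells, the cells of D316 to D434 alone, leaving out 6 cells with Cyp2g1 or Cd3g at an FPKM of at least 100, leaving out 9 cells with S100a9 at an FPKM of at least 100, and setting to 0 each Olfr value under 1% of the highest of its gene in any library. Control sequences entered no comparison. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.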

Results

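RNA sequencing was used to measure gene expression in 85 single cells picked by hand from the dissociated olfactory epithelium of C57BL/6 mice. The stated interest was how sensory neurons come to express odorant receptor genes, named Olfr in the mouse, as they develop. The labels place 11 cells in the Progenitor stage, 9 in the Precursor stage, 27 in the Early Immature Neuron stage, 13 in the Late Immature Neuron stage and 25 in the Mature Neuron stage. A further 8 libraries were technical repeats of 8 of these cells (3 Early Immature Neuron, 3 Late Immature Neuron and 2 Mature Neuron cells) and entered only the comparison of repeats and the alternatives that use them. Each library is 1 cell and no label names an animal, so a stage counts as 1 sample: no test was made between stages, and each SD is a spread over cells. The labels do not say how the stage of a cell was set, and the same transcriptomes may have served for it, so stage markers are not independent evidence of the stages.

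By the depth recovered from the spacing of low values, an FPKM of 1 in a transcript of 1 kb stood for 0.556 to 9.83 fragments, depending on the library. The median was 6.13 fragments in Progenitor, 6.85 in Precursor, 5.70 in Early Immature Neuron, 5.08 in Late Immature Neuron and 4.19 in Mature Neuron cells. The median number of genes at an FPKM of at least 1 was 4794 in Progenitor, 3879 in Precursor, 4128 in Early Immature Neuron, 4531 in Late Immature Neuron and 3536 in Mature Neuron cells. Mitochondrial genes held a median of 44.4% of the FPKM sum in Progenitor cells and 67.0% in Mature Neuron cells. The numbers in the cell names fall into 4 ranges, D29 to D97, D168 to D205, D213 to D274 and D316 to D434, with 6, 19, 23 and 37 cells. Only the range D316 to D434 held all 5 stages, with 3 Progenitor, 5 Precursor, 19 Early Immature Neuron, 6 Late Immature Neuron and 4 Mature Neuron cells.

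Odorant receptor RNA was scarce in Progenitor cells and stood at a high level in most cells from the Early Immature Neuron stage on. A top receptor at an FPKM of at least 100 was found in 24 of 27 Early Immature Neuron, 12 of 13 Late Immature Neuron and 24 of 25 Mature Neuron cells. The number of Olfr genes at an FPKM of at least 1 was 0.636 ± 0.924 per cell (SD, n = 11 cells) in Progenitor and 2.56 ± 2.13 (n = 9) in Precursor cells. It was 7.22 ± 4.41 (n = 27) in Early Immature Neuron, 9.15 ± 6.52 (n = 13) in Late Immature Neuron and 9.64 ± 3.11 (n = 25) in Mature Neuron cells. At least 1 such gene was found in 4 of 11 Progenitor cells (36.4%, exact Clopper-Pearson 95% interval 10.9 to 69.2), in 8 of 9 Precursor cells and in all cells of the 3 neuron stages. Within the range D316 to D434 the Progenitor mean was 2 and the Precursor mean 1.6. At this level the contrast between Progenitor and Precursor cells was thus not seen in that range. It was seen in D168 to D205, where the Precursor cells D178, D179 and D195 held 4, 0 and 4. The Progenitor cell D172 held 1 there, and D169, D170, D174, D175, D184, D189 and D203 held 0. All such intervals cover counting error only. The order of the stages depended on the level asked for. At an FPKM of at least 100, the mean was 0.111 in Precursor, 1.70 ± 1.38 in Early Immature Neuron, 1.62 ± 1.98 in Late Immature Neuron and 1.28 ± 0.614 in Mature Neuron cells. No Progenitor cell had such a gene, which allows a share of up to 28.5%. Many low values belonged to receptors that led other libraries. Of 294 values at an FPKM of 1 to 10 in cells with a top receptor of at least 100, 74.5% were at least 100 times higher in another library of the same number range. A stricter count, chosen after the data were seen, took values at an FPKM of at least 10 and at least 1% of the highest of the gene. It gave 0 in Progenitor, 0.333 ± 0.5 in Precursor, 3.74 ± 3.82 in Early Immature Neuron, 2.31 ± 3.04 in Late Immature Neuron and 1.88 ± 1.13 in Mature Neuron cells. At an FPKM of at least 10 alone the mean was 3.89 in Early Immature Neuron and 3.52 in Mature Neuron cells. Most of the difference between these 2 stages thus came from the 1% rule. The Late Immature Neuron mean leaned on D230, which held 12 by the stricter count and 8 at an FPKM of at least 100. In the range D316 to D434 the Precursor cells D319 and D345 held 1 each by the stricter count. With the 1% rule alone, the Late Immature Neuron cell D205 and the Early Immature Neuron cell D357 held 0 receptors at an FPKM of at least 1.

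Several receptors at a high level were seen most often in Early Immature Neuron cells. At least 3 Olfr genes at an FPKM of at least 100 were found in 8 of 27 Early Immature Neuron cells (29.6%, 13.8 to 50.2). They were found in 1 of 13 Late Immature Neuron cells (7.69%, 0.195 to 36.0) and in 1 of 25 Mature Neuron cells (4%, 0.101 to 20.4). The intervals overlap. Without 6 cells that also held high levels of genes of other cell types, the counts were 7 of 25 Early Immature Neuron, 0 of 12 Late Immature Neuron and 1 of 22 Mature Neuron cells. Within the range D316 to D434 the counts were 5 of 19 Early Immature Neuron, 0 of 6 Late Immature Neuron and 0 of 4 Mature Neuron cells.

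**Figure D1:**
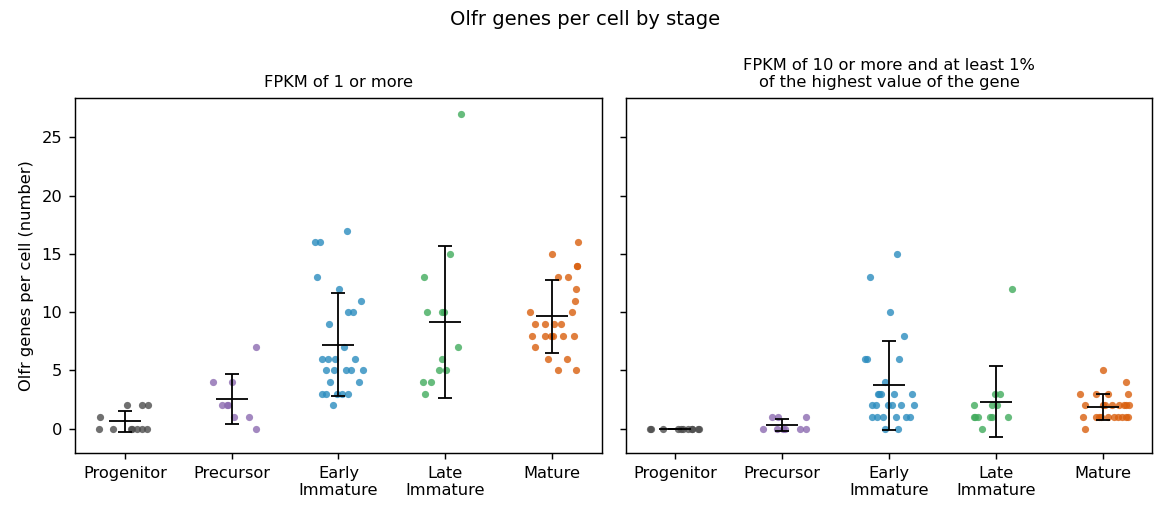
Number of Olfr genes per cell (vertical axis) in each of the 5 stages (horizontal axis), at an FPKM of at least 1 in the first panel and, in the second, at an FPKM of at least 10 and at least 1% of the highest value of the gene. Each point is 1 cell and the bars are the mean and SD over cells. The means run from 0.636 in Progenitor to 9.64 in Mature Neuron cells in the first panel, and in the second are 3.74 in Early Immature Neuron and 1.88 in Mature Neuron cells. At an FPKM of at least 10 without the 1% rule the means of these 2 stages were 3.89 and 3.52.

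The level of receptor RNA was higher in the 3 neuron stages than in Progenitor and Precursor cells. The dominance of 1 receptor was higher in Late Immature and Mature Neuron cells than in Early Immature Neuron cells. The summed Olfr FPKM had a median of 0.325 in Progenitor, 13.1 in Precursor, 1076 in Early Immature Neuron, 2569 in Late Immature Neuron and 6938 in Mature Neuron cells. These sums were not corrected for the total FPKM of a library, which differed widely between cells. The order of the Late Immature and Mature Neuron medians was therefore not settled. The Progenitor median was 1.11 when D169, D174, D175, D184 or D203 was left out and 1.08 without D189, and the Precursor median was 8.63 without D195, D242, D319 or D345. Within the range D316 to D434 these medians were 4.18 for Progenitor, 4.11 for Precursor, 1164 for Early Immature Neuron, 1806 for Late Immature Neuron and 2103 for Mature Neuron cells. The Progenitor and Precursor medians were thus nearly level there, but single cells were not. The Precursor cells D319 and D345 had sums of 123 and 76.2. The Progenitor cells D330, D337 and D393 of that range had 4.07, 4.18 and 11.8. The top Olfr gene of a cell held a median of 81.8% of its Olfr FPKM in Early Immature Neuron, 97.6% in Late Immature Neuron and 98.5% in Mature Neuron cells. In the 4 Progenitor and 8 Precursor cells with a receptor at an FPKM of at least 1, it held 38.4% and 45.1%. These low shares rest mostly on low values. In the 3 Precursor cells with a receptor at an FPKM of at least 10 the median share was 96.99%. Of these cells D319 had 97.1%, D345 96.99% and D242 36.2%. With the 1% rule the Precursor median was 100%. The ratio of the top to the second receptor had a median of 5.81 in Early Immature Neuron, 105 in Late Immature Neuron and 145 in Mature Neuron cells. The ratios were smaller, in the same order, where only receptors at an FPKM of at least 100 counted (1.38, 7.65 and 16.6, in cells with at least 2 such receptors) and in the authors' receptor table (1.54, 8.96 and 11.8). Inside the range D316 to D434 it was 11.4 in Early Immature Neuron, 194 in Late Immature Neuron and 182 in Mature Neuron cells. A top receptor at an FPKM of at least 1000 was found in 10 of 27 Early Immature Neuron (37.0%), 12 of 13 Late Immature Neuron (92.3%) and 22 of 25 Mature Neuron cells (88%).

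**Figure D2:**
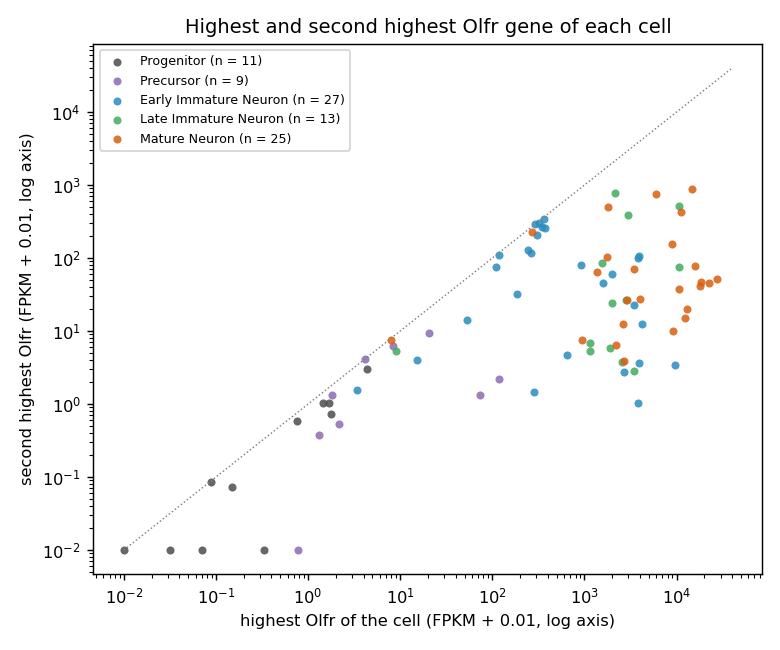
FPKM of the top Olfr gene of each cell (horizontal axis) against that of the second (vertical axis), both as FPKM plus 0.01 on log scales. Each point is 1 cell, coloured by stage, and the dotted line marks equal values. Early Immature Neuron cells lie nearest that line among the neurons, with a median ratio of 5.81 against 145 in Mature Neuron cells.

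Among the Early Immature Neuron cells with most receptors, D318 had 15 Olfr genes at an FPKM of at least 10, led by Olfr457 (mm10 chromosome 6, 42467972 to 42469470) at 264.97 and Olfr1102 at 117. D332 had 13, and its first and second receptors were nearly level: Olfr1222 (chromosome 2, 89124794 to 89125775) stood at 289 and Olfr788 at 288. D411 had 10, led by Olfr467 (chromosome 7, 107814560 to 107815572) at 247. D424 had 8, of which 6 were at an FPKM of at least 100, led by Olfr1431 (chromosome 19, 12210753 to 12211952) at 302. In the Late Immature Neuron stage, D230 had 18, led by Olfr60 (chromosome 7, 140343807 to 140344680) at 2152 and Olfr810 at 782, and it also held the sustentacular cell genes Cbr2 at 3764 and Cyp2g1 at 280. The Mature Neuron cell D232 had its first and second receptors near each other, Olfr398 (chromosome 11, 73983662 to 73990059) at 273 and Olfr147 at 230. In D97 Olfr743 (chromosome 14, 50533414 to 50534349) stood at 14556 with Olfr1229 second at 877. These levels are FPKM of single cells without replicates. Over all cells with a top receptor at an FPKM of at least 100, 61 cells held 60 different top receptors. Olfr726 (chromosome 14, 50079267 to 50085227) led both the Early Immature Neuron cell D431 at 1580 and the Mature Neuron cell D316 at 1740. The top receptor was low in the Late Immature Neuron cell D205 (Olfr860 at 9.03, which stood at 9610 in D192) and in the Mature Neuron cell D329 (Olfr1384 at 7.84). It was low, too, in the Early Immature Neuron cells D347 (Olfr325 at 3.39), D357 (Olfr1384 at 15.0) and D215 (Olfr78 at 53.6).

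Receptors found in the same cell lay near each other on the chromosome more often than random receptors did. Of pairs of Olfr genes of a cell at an FPKM of at least 1, 9.46% lay within 1 Mb, averaged over 74 cells. In 10000 draws of as many Olfr genes the mean was 3.93%, with 95% of draws between 2.51 and 6.13%. The share on the same chromosome was 17.1% against 11.95%. In these draws each cell was drawn on its own, although cells of a number range shared low receptors. When the positions of the receptors were shuffled once for all cells, a setting chosen after the data were seen, the share on the same chromosome lay within the central 95% (7.45 to 18.98). The share within 1 Mb lay above it (1.85 to 8.44). In Mature Neuron cells 10.2% of pairs lay within 1 Mb, in Early Immature Neuron cells 6.80% and in Late Immature Neuron cells 4.37%. The draws for these had means of 3.93%, 3.94% and 3.93%, and at this level only the value of Mature Neuron cells lay outside their central 95%, as it did with shuffled positions (1.73 to 7.20). At an FPKM of at least 10, pairs within 1 Mb made up 22.8% against 3.75%, and all 3 stages lay outside. The shares were then 22.1% in Early Immature Neuron (draws 0.691 to 11.1), 19.5% in Late Immature Neuron (0.280 to 17.3) and 24.4% in Mature Neuron cells (0.582 to 10.99). The Late Immature Neuron share rested on 7 cells, weighted equally. The cell D432 had 2 such receptors, Olfr55 and Olfr239, 18.3 kb apart, so its only pair carried the full weight of a cell. Olfr239 shared 68.3% of its short sequence words with Olfr55, so shared reads stay open for that pair. They stay open, too, for pairs counted in the other 2 stages. In Mature Neuron cells Olfr988 shared 24.7% with Olfr987 (D255) and Olfr1287 22.3% with Olfr1283 (D265). Olfr725 shared 16.5% with Olfr726 in the Mature Neuron cell D316 and the Early Immature Neuron cell D431. The share without D432 was not computed. When draws were taken from all annotated Olfr genes, the share on the same chromosome lay within the central 95% of the draws (14.4% on average, 11.2 to 18.3).

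Between Progenitor and Precursor cells, genes of neural progenitors and of division were lower and genes of early neurons were higher in Precursor cells. The stem cell transcription factor gene Sox2 differed by -4.32 in mean log2(FPKM + 1). Of the progenitor genes, 7 of 8 measured were lower (median -1.31). All 30 measured cell cycle genes were lower (median -1.48), among them Rrm2, a subunit of ribonucleotide reductase (-3.74), Cks2 (-3.61) and the mitotic kinase Aurkb (-3.13). Precursor genes were higher for 6 of 7 (median 1.205), with the neuronal tubulin Tubb3 at 3.01 and the transcription factor Neurod1 at 1.99. Immature neuron genes were higher for 11 of 13 (median 1.78), led by the growth cone gene Gap43 (3.76) and by Dpysl5 (2.45).

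Outside the lists, Ccdc59 (4.34), the co-chaperone gene Sgta (4.09) and the caspase gene Casp6 (3.90) were among the genes highest in Precursor over Progenitor cells. Those lowest included S100a9 (-4.95) and S100a8 (-4.60), which are abundant in neutrophils. Also among them were the immediate early gene Fos (-4.51), Chrac1 (-4.43), the mitochondrial enzyme gene Idh2 (-4.06) and the kinetochore gene Spc25 (-3.88). S100a9 and S100a8 stood at an FPKM of at least 100 in 9 libraries, 8 Progenitor cells and the Precursor cell D179, all numbered D168 to D205. They were at an FPKM of at least 1 in 0 of the other 11 cells of these stages. Of the 15 blood and immune cell genes only S100a9, S100a8 and Lyz2 were measured, and all 3 were lower (median -4.60). Lyz2, too, was at an FPKM of at least 1 in these 9 libraries and in 0 of the other 11 cells. This median thus rested on the same libraries and does not speak for the rest of the list. Sustentacular cell genes were lower for 7 of 8 (median -1.46, with the keratin Krt8 at -3.06). So were dissociation stress genes for 6 of 6 (median -1.76). Gland and microvillous cell genes (median -0.93) and other chemosensory genes (median -1.31, with the G protein subunit gene Gnao1 higher by 2.40) lay within the central 95% of random lists.

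The mature neuron and odorant transduction genes were higher in Precursor than in Progenitor cells for 7 of 7 measured (median 1.08), but the median was -1.60 within the range D316 to D434 and 0.01 without the 9 cells with high S100a9. For the regulators of receptor choice and expression, 13 of 18 were higher (median 0.73), with a median of -0.56 within that range and -0.01 without those cells. Leaving out the Precursor cell D398 alone gave 0.36, and leaving out the Progenitor cell D189 gave 0.43. Their largest difference was Ebf2 at 2.23. Axon guidance genes had a median of 1.36 (4 of 5 higher), synapse genes 1.32 (5 of 5 higher) and cilia genes 0.56 (10 of 13 higher). The median was 0.56 for unfolded protein response genes (9 of 13 higher), -0.25 for chromatin regulators (14 of 25 lower) and 0.08 for housekeeping genes, against -0.03 for all 4316 genes compared. The synapse, cilia, unfolded protein response, chromatin and housekeeping medians lay within the central 95% of random lists, and all but the synapse median depended on single cells. Cilia genes had 0.22 and housekeeping genes -0.04 without the Progenitor cell D172, the unfolded protein response 0.16 without D337 and chromatin regulators -0.64 without D203. Within the range D316 to D434 the synapse median was -0.12 and the unfolded protein response median -0.33. The precursor median was 0.52 and the immature neuron median 0.69 in that range, while the progenitor median was -0.68 when the Precursor cell D178 was left out.

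Between Precursor and Early Immature Neuron cells, the machinery of odorant detection was higher and the precursor genes were lower in Early Immature Neuron cells. All 16 measured mature neuron and odorant transduction genes were higher (median 2.72). Among them were the receptor transporter gene Rtp1 by 4.85, the G protein subunit gene Gng13 by 4.19, the olfactory marker protein gene Omp by 4.14 and the cyclic nucleotide gated channel gene Cnga2 by 4.05. Neurod1 had the lowest difference of all genes (-6.26), from 6.89 ± 1.40 (n = 9) in Precursor to 0.63 ± 1.31 (n = 27) in Early Immature Neuron cells. Precursor genes were lower for 6 of 7 (median -2.88; -1.06 without the Precursor cell D374 and -1.84 without D195). Lower, too, were cell cycle genes for 10 of 11 (median -2.92, with Ube2c at -4.18) and progenitor genes for 5 of 5 (median -2.58). Faim, an inhibitor of Fas-mediated cell death (6.60), Mlf1 (5.33), the G protein signalling regulator Rgs11 (5.05), the brain creatine kinase gene Ckb (5.01) and the scaffold gene Homer2 (4.94) were among the genes highest in Early Immature Neuron cells. Those lowest included the nucleotide synthesis enzyme gene Impdh2 (-6.12), Ifitm2 (-5.94), the retinoic acid binding protein gene Crabp2 (-5.90), Mfng, a modifier of Notch (-5.89), and Cd24a (-5.82).

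Regulators of receptor choice and expression were higher in Early Immature Neuron than in Precursor cells for 14 of 22 (median 0.94), including Ebf4 (4.48) and the stress response gene Ddit3 (3.26). Chromatin regulators were lower for 17 of 22 (median -1.25; -0.82 without the Precursor cell D398), among them Lbr, the lamin B receptor gene (-2.96), while the DNA methyltransferase gene Dnmt3a was 2.79 higher. Synapse genes were higher for 8 of 9 (median 1.70, with Snap25 at 2.96), axon guidance genes for 9 of 11 (median 1.42, with Cntn4 at 3.49), and cilia genes for 11 of 16 (median 0.98, with Bbs4 at 2.53). The immature neuron genes went both ways, with 7 higher and 7 lower (median -0.22; 0.05 without the Early Immature Neuron cell D357): Dcx was 3.25 higher and Gnas 2.48 lower. The unfolded protein response genes had a median of 0.02 (0.44 without the Precursor cell D374) and housekeeping genes -0.51, against -0.26 for all 4001 genes. These lists and the immature neuron list lay within the central 95% of random lists.

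Between Early and Late Immature Neuron cells, genes of growing neurites were lower and genes of odorant transduction higher in Late Immature Neuron cells. Omp had a mean log2(FPKM + 1) of 5.94 ± 4.52 (SD, n = 27) in Early Immature Neuron and 12.37 ± 0.67 (n = 13) in Late Immature Neuron cells. In all, 20 of 21 mature neuron and odorant transduction genes were higher (median 3.47), with the stomatin family gene Stoml3 at 6.28, the calcium binding protein gene S100a5 at 6.23 and Umodl1 at 6.04. All 13 immature neuron genes were lower (median -2.96), led by Gap43 (-5.90), the tubulin regulators Stmn1 (-5.72) and Stmn2 (-4.34), and Dpysl3 (-4.21). Outside the lists, Nrn1l (6.54) and Tspan7 (5.76) were among the highest in Late Immature Neuron cells, and Vim, the gene of vimentin (-5.88), Qdpr (-5.42) and Marcks (-4.44) among the lowest. Cilia genes were higher for 19 of 20 (median 1.28), with Arl3 at 3.85 and Bbs5 at 2.80. Axon guidance genes were higher for 11 of 16 (median 1.36), with the adhesion gene Kirrel2 at 4.09 and the guidance receptor gene Nrp1 at -2.21. Synapse genes were higher for 11 of 13 (median 1.57; 0.99 without the Late Immature Neuron cell D250), with Snap25 at 3.83.

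Chromatin regulators were lower in Late than in Early Immature Neuron cells for 12 of 16 (median -0.83; -0.51 without the Late Immature Neuron cell D230 and -0.53 without D334). The lowest were the histone deacetylase gene Hdac2 (-4.79), its partner Rcor1 (-2.60) and the Polycomb gene Suz12 (-2.17). Precursor genes were lower for 4 of 4 (median -1.33, with Insm1 at -2.61). Other medians were 0.78 for 5 cell cycle genes, -0.35 for regulators of receptor choice, 0.39 for the unfolded protein response, -0.92 for 3 dissociation stress genes and -0.38 for housekeeping genes, against 0.41 for all 4138 genes. These lists lay within the central 95% of random lists. The dissociation stress median was between -0.21 and 0.02 when any 1 of the Late Immature Neuron cells D77, D199, D230, D233, D234, D250 and D343 was left out. The regulators had -0.14 without D343, and the unfolded protein response had 0.73 without D199 and 0.20 without the Early Immature Neuron cell D411. When each library was rescaled to the same FPKM sum, the unfolded protein response median was -0.01.

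Late Immature Neuron and Mature Neuron cells were close to each other in the transduction genes. Of these, 17 of 21 were higher in Mature Neuron cells (median 0.41), but the median was -0.51 after rescaling and -0.05 within the range D316 to D434, so their direction was not settled. The phosphodiesterase gene Pde4a was 1.36 higher and the exchanger gene Slc24a4 0.96 lower before rescaling. Immature neuron genes were lower for 11 of 12 (median -1.28, within the central 95% of random lists), including Tubb3 (-2.40; 0.08 within the range D316 to D434) and Dpysl3 (-1.68), while Stmn2 was 1.50 higher. The intraflagellar transport genes Ift74 (2.19) and Ttc30b (2.11), with Bola1 (2.55) and Rbm6 (2.24), were among the highest in Mature Neuron cells. The intraflagellar transport genes Ift20 (-2.64) and Ift57 (-2.01) were lower, as were 17 of 23 cilia genes. Among the lowest were Mtch2 (-4.09), Rabl2 (-3.94), Ergic3 (-3.71) and the palmitoyltransferase genes Zdhhc12 (-3.68) and Zdhhc13 (-3.41). Sustentacular cell genes were higher for 4 of 4 (median 0.97; 1.49 without the Late Immature Neuron cell D230), with Cbr2 at 1.85 and Cyp2g1 at 1.199. The median over all 3831 genes was -0.58. The 4 cell cycle genes had a median of -1.35, which was between -0.65 and -0.53 when any 1 of the Late Immature Neuron cells D77, D199, D230, D233, D250, D334 and D432 was left out. The median was -0.46 for cilia genes, -0.47 for chromatin regulators, -0.40 for axon guidance genes, -0.35 for synapse genes and -0.36 for dissociation stress genes. Regulators of receptor choice had -0.07, the unfolded protein response -0.07 and housekeeping genes 0.09, which were -0.95, -0.86 and -0.82 after rescaling. These lists, from cell cycle to housekeeping, lay within the central 95% of random lists, and each depended on single cells, with synapse genes at -0.66 without D230 and the unfolded protein response at 0.09 without D233.

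From Progenitor to Mature Neuron, genes of transduction were higher and genes of division lower by the largest amounts among the lists, apart from the 3 blood and immune genes and the progenitor genes. Omp (chromosome 7, 98143360 to 98145502) had a median FPKM of 0 in Progenitor and 6257 in Mature Neuron cells, a difference of 12.11 in mean log2(FPKM + 1), followed by Stoml3 (11.11), Ctxn3 (9.98), S100a5 (9.78) and Plekhb1 (9.67). All 20 measured mature neuron and odorant transduction genes were higher (median 7.37). Higher, too, were 10 of 10 synapse genes (median 3.06, with Snap25 at 8.67), 9 of 11 axon guidance genes (median 2.57, with Cntn4 at 6.20) and 18 of 20 cilia genes (median 1.99, with Arl3 at 4.63). All 30 cell cycle genes were lower (median -4.04), among them the mitotic genes Ube2c (-7.86), Birc5 (-6.28) and Top2a (-5.56). Lower too were 8 of 8 progenitor genes (median -4.62), with the Notch pathway gene Hes6 at -7.12, and 6 of 6 precursor genes (median -3.52). The same held for 10 of 13 immature neuron genes (median -2.48) and 24 of 25 chromatin regulators (median -2.004), with the Polycomb methyltransferase gene Ezh2 at -6.09. Fabp5 (-7.00) was at an FPKM of at least 1 in all 11 Progenitor cells and in 0 of 25 Mature Neuron cells.

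The median of all 4463 genes compared was -0.81 from Progenitor to Mature Neuron, and rescaling each library to the same FPKM sum moved it to -1.67. Within the range D316 to D434 it was 0.14, so its direction was not settled. Rescaling also moved the median from Late Immature Neuron to Mature Neuron to -1.17 and that from Early to Late Immature Neuron from 0.41 to 0.07. Against these, unfolded protein response genes had a median of 0.79, which was -0.44 after rescaling and 0.44 without the Progenitor cell D330. Regulators of receptor choice had -0.31, which was -1.68 after rescaling and 0.07 without the Progenitor cell D172. Sustentacular cell genes had 0.13, which was -0.34 after rescaling and -0.00501 without the Progenitor cell D337 or D393, and housekeeping genes -1.02, which was -2.21. The blood and immune list, of which only S100a9, S100a8 and Lyz2 were measured, had a median of -5.41 (3 of 3 lower). Leaving out the Progenitor cells D170, D174, D184 or D189 in turn gave -3.53, -3.60, -3.57 and -3.55. Gland and microvillous cell genes had -1.08, dissociation stress genes -1.84 and other chemosensory genes -1.55, with Gnai2 at -3.99 and Gnao1 at 3.17. Of the lists in this paragraph, only the blood and immune list lay outside the central 95% of random lists.

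**Figure D3:**
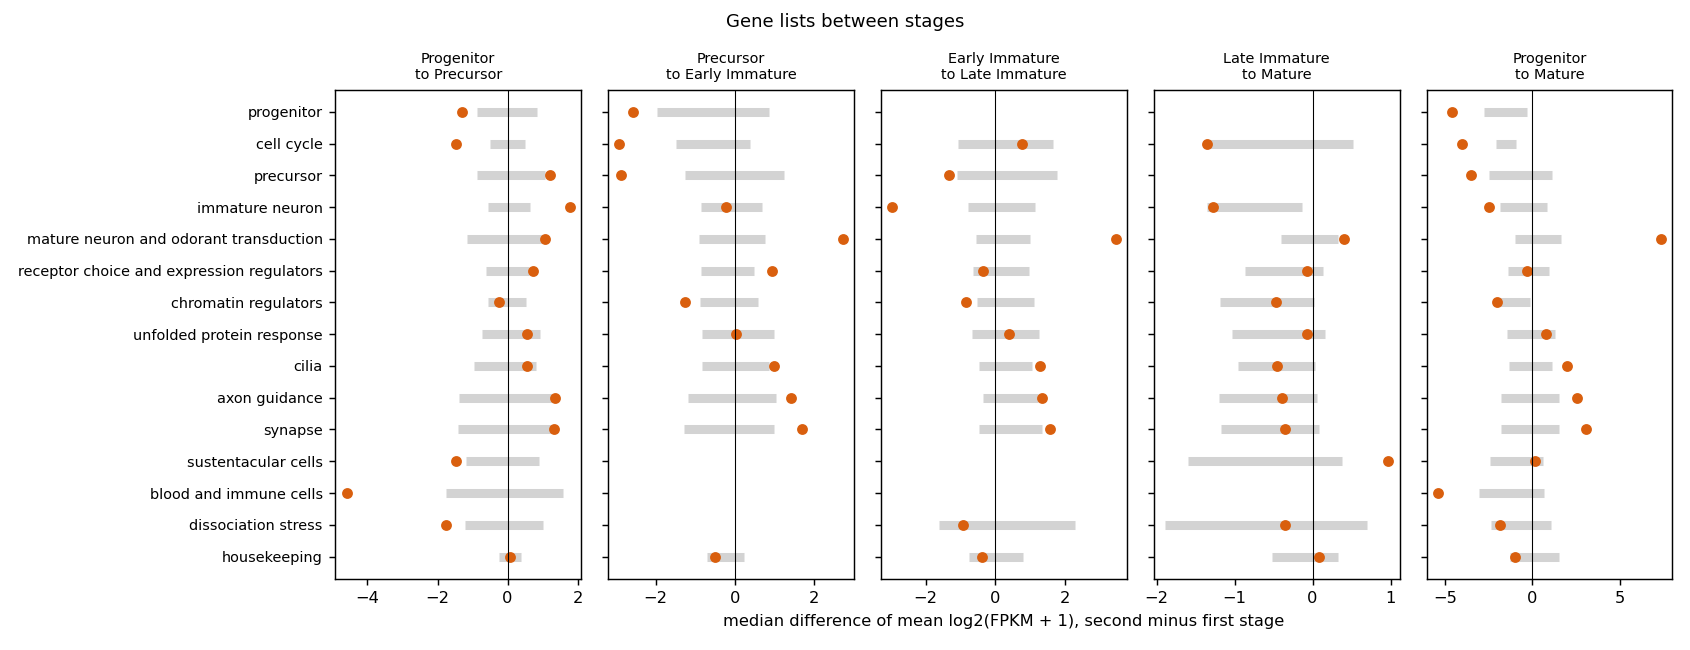
Median difference of mean log2(FPKM + 1), second stage minus first (horizontal axis), for gene lists (vertical axis) with at least 3 measured members in a pair of stages. The gland and microvillous and the other chemosensory lists are not drawn. Dots are lists and grey bars hold 95% of 10000 random lists of the same size and like expression. The mature neuron list reaches 7.37 from Progenitor to Mature Neuron, and 0.41 from Late Immature Neuron to Mature Neuron, which is -0.51 after rescaling.

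Regulators linked to receptor choice followed different courses over the stages. Lbr (chromosome 1, 181815316 to 181842401) was at an FPKM of at least 1 in 9 of 11 Progenitor and 6 of 9 Precursor cells. It was so in 1 of 27 Early Immature Neuron, 1 of 13 Late Immature Neuron and 1 of 25 Mature Neuron cells. Kdm1a, a histone demethylase gene (chromosome 4, 136550540 to 136602723), had a mean log2(FPKM + 1) of 3.86 ± 2.33 in Progenitor, 5.34 ± 1.55 in Precursor and 3.34 ± 2.57 in Early Immature Neuron cells. It had 1.45 ± 1.87 in Late Immature Neuron and 0.83 ± 1.86 in Mature Neuron cells. Atf5, a transcription factor gene of the unfolded protein response, had means of 4.50, 5.52, 7.83, 8.68 and 8.62 in the same order. Lhx2, a transcription factor gene of sensory neurons, was highest in Precursor cells, with median FPKM of 93.2, 514, 145, 128 and 79.5. The transporter genes Rtp1 (0.238, 0.354, 146, 346.6 and 384) and Rtp2 (0, 3.81, 102, 293 and 392) had high medians from Early Immature Neuron cells on, and the adenylyl cyclase gene Adcy3 (0, 0.0674, 1.51, 60.6 and 89.9) from Late Immature Neuron cells on. Gap43 had medians of 0.186, 38.8, 360, 1.19 and 0, and Gng8, a G protein subunit gene of immature neurons, 1.39, 19.4, 29.2, 1.38 and 0. Emx2 and Ebf1 were highest in Early Immature Neuron cells, with means of 6.29 ± 2.39 and 6.40 ± 1.69. Neurog1 was at an FPKM of at least 1 in 5 of 11 Progenitor, 4 of 9 Precursor and 1 of 27 Early Immature Neuron cells.

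**Figure D4:**
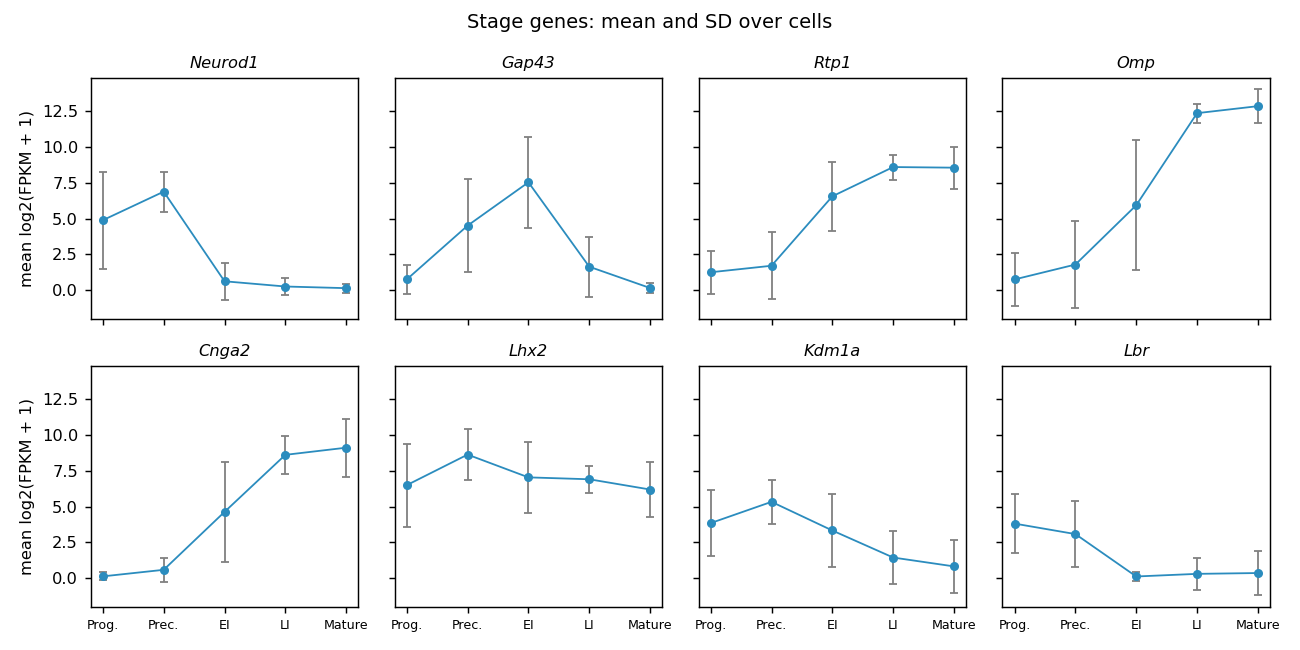
Mean log2(FPKM + 1) over cells (vertical axis) of Neurod1, Gap43, Rtp1, Omp, Cnga2, Lhx2, Kdm1a and Lbr in the 5 stages (horizontal axis; EI and LI are the Early and Late Immature Neuron stages), with bars for the SD over cells. Neurod1 has a mean of 6.89 in Precursor and 0.63 in Early Immature Neuron cells, and Omp 0.75 in Progenitor and 12.86 in Mature Neuron cells.

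In the 8 cells with 2 libraries, the receptor that led the first library also led the repeat in 5. The labels do not say at which step a repeat was split off, so these values do not tell the content of a cell from noise of a library. The top receptor Olfr325 of the Late Immature Neuron cell D233 (chromosome 11, 58581837 to 58582336) stood at 10652 and 13725, and Olfr728 of the Mature Neuron cell D243 at 8831 and 2111. The value of 8831 was that of an assembled entry of only 133 bp, the highest of 3 entries of Olfr728, so this level is uncertain. In the Early Immature Neuron cell D187 the first library was led by Olfr876 at 110 and the repeat by Olfr917 at 314, each listed at 0 in the other library. D200 was led by Olfr610 at 320, listed at 0 in the repeat, and then by Olfr570 at 850, which stood at 305 in the first. Of 22 Olfr genes at an FPKM of at least 100 in the first libraries and 18 in the repeats, 13 were the same. At an FPKM of at least 1 the numbers were 103, 110 and 34. At 100 the Early Immature Neuron cells repeated least. D187 had 1 and 3 with 0 the same, D200 had 3 and 2 with 1 the same, and D244 had 3 and 3 with 2 the same. In D230, D233, D243, D250 and D251 every receptor of the repeat at this level was also in the first library. Annotated genes at an FPKM of at least 10 in 1 library of a cell were sought at an FPKM of at least 1 in its other library. Averaged over both directions, a median of 61.6% (55.1 to 78.4) were found. Taken the same way between the first library and other cells of the same stage, the median was 60.4% (56.7 to 63.8). Only in D230 (68.2% against 65.9%) and D244 (78.4% against 68.4%) was the repeat above the nearest other cell of the stage. For genes at an FPKM of at least 1 or 100 this held in D244 only. D230 had 60.9% against 62.9% and 75.9% against 81.8%. Both D230 and D244 also held Cyp2g1 at an FPKM of at least 100.

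Genes of other cell types were present in each stage. In 6 cells, picked out after their values were seen, the sustentacular gene Cyp2g1 or the T cell gene Cd3g stood at an FPKM of at least 100. Cyp2g1 stood at 574 and Cbr2 at 2436 in the Early Immature Neuron cell D244, and Cd3g at 805 in the Early Immature Neuron cell D357. Cbr2, an enzyme gene of sustentacular cells, was at an FPKM of at least 10 in 72.7% of Progenitor, 29.6% of Early Immature Neuron, 46.2% of Late Immature Neuron and 64% of Mature Neuron cells. In Precursor cells no sustentacular gene was so in more than 22.2%. The median sustentacular gene was at that level in 0% of Progenitor, 11.1% of Precursor, 7.41% of Early Immature Neuron, 15.4% of Late Immature Neuron and 8% of Mature Neuron cells. The median gene of the horizontal basal and of the blood and immune lists was so in 0% of cells of each stage. Gland and microvillous genes had a median share of 3.70% in Early Immature Neuron cells, and stromal and endothelial genes 1.85%. Glia and ensheathing genes had 3.70% in Early Immature Neuron and 4% in Mature Neuron cells. In the other stages these median shares were 0%.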

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

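The tests of carry-over for low receptor values, of 2 neurons in a tube, of expression in Progenitor cells and of a shared source were chosen only after the result was seen.

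Several Olfr genes stood at an FPKM of at least 10 in Early Immature Neuron cells, with 13 of 27 cells holding at least 3 and 7 holding at least 5 that also were at least 1% of the highest of the gene; at least 3 were also held by 3 of 13 Late Immature Neuron and 6 of 25 Mature Neuron cells, and by 12 of 25 Early Immature Neuron cells without those with genes of other cell types. Without the 1% rule the mean at an FPKM of at least 10 was 3.89 in Early Immature Neuron and 3.52 in Mature Neuron cells. Carry-over between libraries would need the receptors of Early Immature Neuron cells to be far higher elsewhere. Of 79 values beside the top receptor, 3.80% were 100 times higher in another library of the same number range. Carry-over of more than 1% would not meet this rule and was not tested. Reads shared between near copies would need shared sequence. Of the 79, 2.53% had 10% or more of their words of 50 bases in a higher receptor of the cell. Smaller shared parts were not counted, so shared reads stay open for values far below a higher receptor. Tubes with 2 neurons cannot be told apart from neurons with several receptors: 1 Olfr gene per neuron would not give the 13 cells with at least 3, but 14 of 25 Mature Neuron cells held at least 2 as well, so that premise is open. Carry-over of more than 1%, tubes with more cells, and co-expression of several receptors as a feature of the stage, stay open and untested.

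Olfr genes at an FPKM of 1 to 10 were common in cells with a top receptor of at least 100. Carry-over from other libraries may account for most: 74.5% of 294 values were at least 100 times higher in another library of the same number range, against a mean of 1.59% when the other ranges were searched. Olfr168 was low in 10 cells, all of D213 to D274, where D253 had 10731 and Olfr1257 in 9 cells, all of D316 to D434, where D433 had 9156, but Olfr613 was low in 12 cells of 3 ranges with a highest value of 8.93, and Olfr1384 in 12 cells of 3 ranges with its highest value, 3886, in D425. Of 284 values, 2.11% shared 10% or more of their sequence words with the top receptor. Smaller shared parts were not counted and could matter at such low values, so reads shared with the top receptor stay open. The remaining low values, and whether they are expression, stay open.

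S100a8 and S100a9 were higher in Progenitor than in Precursor cells. Expression in Progenitor cells cannot be told apart from a feature of the range D168 to D205: 0 of 3 Progenitor cells of D316 to D434 had S100a9 at an FPKM of at least 10 (up to 70.8% allowed), but all 8 of D168 to D205 did (at least 63.1%), while 0 of 10 other cells of that range outside the 9 libraries had it at 1. A shared source of RNA stays open as well: the SD of log2 S100a8 over the 9 libraries was 0.31, against a median of 0.60 for 6 genes of like level, itself included, that stood at 100 or more in each of them, too few to decide, and that of S100a9 was 0.40 against 0.54 for 15. Of 14 neutrophil genes set down as not looked at before, 4, among them Lcn2 (median 7.27) and Mmp8 (4.17), were in at least 8 of the 9 libraries and in no other Progenitor or Precursor cell, while Mpo and Elane were listed at 0. Ltf, also among the 4, belongs to the fixed gland and microvillous list as well. It differed there by -1.32 from Progenitor to Precursor, so it was not new to this test. Camp (median 49.1), Ngp (34.8), Retnlg (10.3) and Lyz2 (7.02), seen before this test, were in 9 of 9 and in 0 of the 11 other cells, but Cyp2g1 (2.53), a gene of sustentacular cells, was in 9 of 9 as well, so whether neutrophil RNA was the source stays open.

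Of 24 groups of 4 to 10 values examined, 4 held a value far from the rest, where chance gives about 1 in 20. Among the 4 Progenitor cells with a receptor at an FPKM of at least 1, D172 had 70.8% of its Olfr FPKM in its top receptor, with the next at 40.1% (gap 0.858 of the range). Among the 9 Precursor cells, D242 had the highest Omp (log2 8.57, next 3.93; 0.542 of the range), D398 the highest Adcy3 (4.27, next 2.08; 0.512) and D383 the lowest Lhx2 (4.37, next 7.61; 0.540).

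A control sequence named ERCC_vector, which entered no comparison, stood above the level that 3 fragments allow in 10 libraries: at an FPKM of 6.60 in D203, 4.40 in D199, 1.99 in D172, 1.21 in D170, 0.573 in D184, 0.441 in D192, 0.254 in D97, 0.171 in D175, 0.164 in D29 and 0.123 in D77.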

How the results depend on the processing

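No paired analysis was possible because no label links cells of different stages. Of 272 values of receptor measures under other settings, 236 lay within 1 SD over cells of the value reported, as did 763 of 805 list values, 2824 of 2976 values of named genes and 57 of 58 medians of all genes. Fewer stayed that close for co-location (5 of 11, by the width of the random draws) and for genes per cell and the genes seen again in repeats (1 of 12). Leaving out cells of few genes removed 0 cells, and no value was moved beyond that spread by leaving out 1 cell, by the mean of both libraries or by leaving out Olfr pseudogenes. Leaving out 1 cell turned no list outside the central 95% of random lists, but it turned others: from Progenitor to Precursor the median of all genes went from -0.03 to 0.11 without D242, from Precursor to Early Immature Neuron that of immature neuron genes from -0.22 to 0.05 without D357, from Early to Late Immature Neuron that of dissociation stress genes from -0.92 to 0.02 without D199, and from Progenitor to Mature Neuron that of regulators of receptor choice from -0.31 to 0.07 without D172. Depth limits the low counts, since an FPKM of 1 can rest on a single fragment in the shallowest library. The cause of the differences listed here was not tested, except that a higher threshold counts fewer genes and a larger pseudocount shrinks differences by construction. The settings on D316 to D434, S100a9 cells, shuffled positions and the 1% rule were chosen after seeing the data.

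Olfr genes per cell above an FPKM of 0 were 4.91, 10.7, 15.6, 15.8 and 15.8 (Progenitor to Mature Neuron), and genes per cell 8968, 7687, 8236, 8460 and 7324. At least 5 gave 4.52 Olfr genes in Mature Neuron cells. At least 10 gave 0.333 in Precursor and 3.52 in Mature Neuron cells, a top share of 96.99% in Precursor cells, 33.6% of pairs on the same chromosome and 22.8% within 1 Mb, and 3115, 2725, 2969, 3064 and 2243 genes per cell. At least 100 gave 0.111, 1.70, 1.62 and 1.28 Olfr genes (Precursor to Mature Neuron), a top share of 97.1% in Precursor cells, top to second ratios of 7.65 in Late Immature Neuron and 16.6 in Mature Neuron cells, and 75.2% of genes seen again in repeats. The authors' receptor table gave 0.111, 2.78, 1.77 and 1.24, a top share of 100% in Precursor cells, ratios of 8.96 and 11.8 for the same later stages, and median sums of 0 in Progenitor and 0 in Precursor cells. Under the 1% rule, Olfr genes were 0.333 in Precursor and 3.16 in Mature Neuron cells, the top share 100% in Progenitor and Precursor cells, and the sums 0 and 0.104; with an FPKM of at least 10 the rule gave 0.333 in Precursor, 2.31 in Late Immature Neuron and 1.88 in Mature Neuron cells. A window of 100 kb held 6.42% of pairs, and leaving out pairs within 50 kb left 7.40%.

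Cells of D316 to D434 alone gave 2 Olfr genes in Progenitor cells and a ratio of 54.1 in Precursor cells. There, from Progenitor to Precursor, the mature neuron list was reversed to -1.60 and the regulators of receptor choice to -0.56; from Late Immature Neuron to Mature Neuron the mature neuron list was reversed to -0.0465 and Tubb3 to 0.0773; from Progenitor to Mature Neuron all genes had 0.14 and the mature neuron list 5.90. Without the cells with high S100a9 the regulators were reversed to -0.00535 and the mature neuron list had 6.70 from Progenitor to Mature Neuron. Rescaling reversed the mature neuron list to -0.51 from Late Immature Neuron to Mature Neuron and gave it 5.96 from Progenitor. For this last pair, a pseudocount of 0.1 gave 9.61 for mature neuron, -6.40 for cell cycle and 4.62 for synapse genes, a pseudocount of 10 gave 4.85, -2.07 and 1.70, medians over cells gave 8.39 for mature neuron genes, and no detection filter gave 6.68 for these and 1.26 for synapse genes.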

Other observations

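The comparison of neighbours of the top receptor was chosen only after the result was seen, and nothing in this part was planned. Some receptors beside the top one were its neighbours on the chromosome. Counted were Olfr genes at an FPKM of at least 10 and at least 1% of the highest of the gene, in cells with a top receptor of at least 100. Of those beside the top receptor, 12 of 23 lay within 1 Mb of it in Mature Neuron cells (52.2%), 9 of 75 in Early Immature Neuron cells (12%) and 1 of 18 in Late Immature Neuron cells (5.56%). These shares pool receptors over cells, and a few Early Immature Neuron cells held many receptors. By cells, 10 of 24 Mature Neuron, 8 of 24 Early Immature Neuron and 1 of 12 Late Immature Neuron cells had such a neighbour, so a difference between the Mature and Early Immature Neuron stages was not settled. The 22 neighbours had a median distance of 43.0 kb, and 5 of them shared at least 10% of their words of 50 bases with the top receptor. The top receptor stood at a median of 64.6 times its neighbour. The largest ratio was 2140, for Olfr177 at 10.5 beside Olfr195 in the Mature Neuron cell D55. At such ratios a shared part under 10% could matter, so shared reads stay open for the other neighbours that shared words. Olfr877, Olfr570, Olfr1054, Olfr1034, Olfr1231, Olfr186 and Olfr628 shared 0% of their words of 50 bases with the top receptor of their cell. For these neighbours that argues against shared reads of 50 or more identical bases. Olfr1054 (chromosome 2, 86332416 to 86333354) stood at 496 beside Olfr1055 at 1798 in the Mature Neuron cell D259, Olfr968 at 422 beside Olfr972 at 11159 in D223, and Olfr186 at 98.8 beside Olfr187 at 3858 in the Early Immature Neuron cell D336. Both cells led by Olfr726, D431 and D316, held Olfr725 (46.1 and 62.4) and Olfr727 (33.3 and 37.5). Olfr725 shared 16.5% of its words of 50 bases with Olfr726, and Olfr727 shared 3.79%.

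The 9 libraries with high S100a9 held genes of several other cell types, some at low and even levels and some not. Cyp2g1, an enzyme gene of sustentacular cells, was at an FPKM of at least 1 in 9 of 9 (median 2.53, 1.13 to 5.58), in 1 of the other 11 Progenitor and Precursor cells and in 0 of the 10 other cells of D168 to D205. Cyp2a5 (median 4.47) and Coch (5.59) were so in 9 of 9 and the microvillous cell gene Ascl3 in 8 of 9. Uneven, though also in 9 of 9, were the glial gene Fabp7 (9.96 to 5793), Krt8 (2.29 to 273.8), Krt18 (1.13 to 173) and Cbr2 (22.4 to 478).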
